A study of Mus musculus with 8 samples.

How the data were processed

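RNA-seq read counts of red pulp macrophages sorted by flow cytometry from mouse spleen were used, with 4 libraries taken 2 h after CLP and 4 taken 2 h after sham surgery. Groups and replicate numbers came from the sample titles. Per the labels' protocols, total RNA was isolated with a column kit, libraries were made with a stranded Illumina TruSeq kit, and sequencing was done on an Element AVITI. The values are raw counts per Ensembl gene that the authors deposited as 1 table with 1 column per library. FastQC, STAR 2.7.10b, featureCounts and DESeq2 are named together with the mouse build mm39 in the submitters' processing notes, without their roles. The annotation release and the strand setting of the counting are not given in the sources used here, so reads of genes that overlap on opposite strands, and of near-identical copies such as the hemoglobin genes, cannot be told apart with certainty.

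The table held 55414 gene rows. Of these IDs, 52081 were given symbols from GENCODE mouse release 21, an annotation of an older build used for names, transcript length and GC content only, and 3333 had no symbol (0.19% to 0.912% of the counts of a library). No coordinates are given for that reason. Total counts per library were 15392992 to 25665633, and with TMM scaling a gene at 1 CPM rests on about 15.1 to 27.6 reads per library, and values below that carry large counting error. All pairs of libraries within a group differed by more than sampling noise (lowest chi-square per degree of freedom 9.25). None was therefore treated as a repeat sequencing of another, and each was kept as its own replicate. This does not show that the libraries came from separate mice.

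The counts were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr kept 14004 genes, libraries were scaled by TMM (factors 0.873 to 0.915 in CLP and 1.08 to 1.15 in sham), and the robust quasi-likelihood F-test was fitted on the 2 groups with no covariates. P-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05, and a second count asked for an absolute log2 fold change of at least 1. Log2 fold changes are CLP minus sham, and SE is the absolute log2 fold change divided by the square root of F. CPM values use the TMM-scaled totals and are given as mean ± SD of 4 libraries. The common biological coefficient of variation was 0.182.

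Gene lists, 27 functional and 18 of cell type markers, RNA quality or sex-linked genes, were fixed before the data were examined, as were the tests, the rule for named genes and the alternatives. Lists with at least 5 tested members were tested with camera (limma 3.58.1) on voom values with a preset correlation of 0.01. Counts of higher and lower members use the adjustment over all genes, beside a count adjusted over the list alone. The rule for named genes took the 8 highest and 8 lowest log2 fold changes among changed genes with a mean of at least 5 CPM and no overlap between the groups, leaving out unnamed gene models. From each functional list it took the 3 largest changes at 5 CPM or more and the most abundant member, and from each marker list the most abundant and the most changed member. Hmox1, Slc40a1, Spic, Vcam1, Adgre1, Slc48a1, Tnf, Il1b, Il6, Il10, Nfkbia, Cd163 and Sirpa were always named. Of 702 changed unnamed models or IDs without a symbol, none is named. Values of some genes in the lists are not reported here.

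Principal components were computed on log2 CPM (prior count 2) of the 500 most variable genes. Alternatives were DESeq2 1.42.0, limma-voom with and without sample weights, DESeq2 size factors, library totals, TMM without the marker lists, other filters on low counts, 1 surrogate variable (sva 3.50.0), a replicate block, each library left out in turn, and for lists an estimated correlation, fry, and lists without shared genes. Lists centred on the abundance trend and a filter at a mean of 10 CPM were added after the data were seen. On counts simulated for this comparison from the real means and library sizes (14004 genes, 200 of them changed), the edgeR step recovered 50.7% of genes changed 1.5-fold and 95.5% of those changed 2-fold and 4-fold, and called 12 unchanged genes. The changed genes had at least 5 CPM and were far fewer than the 6064 called in the data. These figures therefore do not measure recovery or false calls in the data. The camera step called the 1 raised list and 0 of 39 unchanged ones. Genes were simulated independently of each other, so this does not test camera on lists whose members vary together. In the real data the estimated correlation within a list reached 0.877. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.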

Results

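Red pulp macrophages, the macrophages of the spleen that take up aged red blood cells and recycle their iron, were sorted from spleens of wild-type C57BL/6J mice 2 h after cecal ligation and puncture (CLP) or after sham surgery. CLP is a surgical model of sepsis in which the punctured cecum leaks gut bacteria into the abdomen. The series asks how sepsis leads to hemolysis, and the 1 comparison its design holds is CLP against sham, with 4 libraries in each group. Total counts lay between 17333748 and 21409078 in the CLP libraries and between 15392992 and 25665633 in the sham libraries. The labels do not say that each library came from a separate mouse, so p-values measure the spread between these samples, which may in part be technical.

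Within 2 h of CLP the macrophages carried far more RNA for inflammatory cytokines, chemokines and NF-kB feedback genes. Of 27 immediate early genes 15 were higher and 6, Fos among them, were lower. Cd14, the co-receptor for bacterial lipopolysaccharide, rose from 878 ± 252 CPM in sham to 7079 ± 988 CPM in CLP (SD, n = 4 each), a log2 fold change of 3.01 (SE 0.23, adjusted p = 1.53e-05 in edgeR's quasi-likelihood test). Il1b rose from 480 ± 127 to 3514 ± 1028 CPM, and Tnfaip3, which encodes the NF-kB inhibitor A20, from 838 ± 190 to 5000 ± 118 CPM. Of 14004 genes tested, 6064 (43.3%) changed, with 2767 higher and 3297 lower after CLP. By at least 2-fold, 2053 changed, 882 higher and 1171 lower. The CPM of both groups did not overlap for 5813 genes (41.5%), where chance gives 2.86%. The first principal component of the 500 most variable genes held 82.2% of the variance and separated all CLP from all sham libraries (two-sided exact permutation p = 0.0286 over 70 assignments, the smallest they allow). The balance of higher and lower genes depended on scaling. With library totals in place of TMM factors the fold changes shifted by a median of -0.32, and 1286 genes were higher and 6435 lower (16.7% higher against 45.6%). Sham replicate 4 stood apart from the other sham libraries in erythroid, cell cycle and inflammatory genes, and without it 2703 genes were higher and 2756 lower. This more even balance was not particular to it, since leaving out Sham replicate 1, 2 or 3 gave 49.9%, 49.4% and 49.4% higher.

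**Figure D1:**
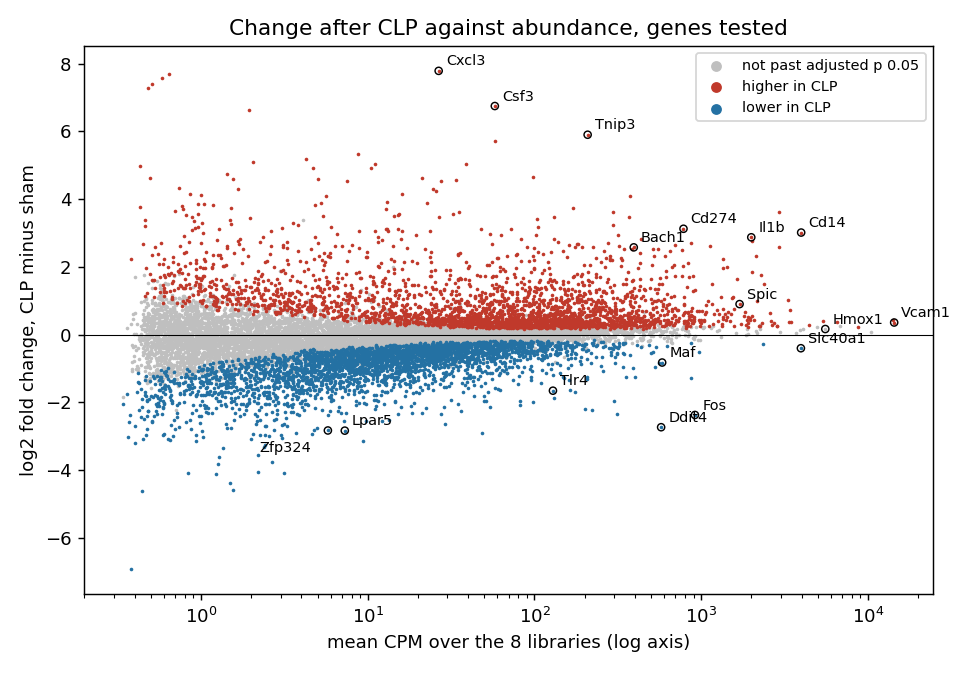
Each point is 1 of 14004 tested genes, with its mean CPM over the 8 libraries on a log axis and its log2 fold change (CLP minus sham) on the other axis. Red genes (2767) were higher and blue genes (3297) lower after CLP at adjusted p under 0.05 with TMM scaling, against 1286 and 6435 with library totals.

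Inflammatory cytokine and chemokine genes had the highest median log2 fold change of the functional lists (2.56), with 31 of 34 tested members higher and 1 lower (31 and 2 adjusted over the list alone, camera adjusted p = 9.37e-16, adjusted p = 0.217 with an estimated correlation). The neutrophil-attracting chemokine Cxcl3 went from 0.226 ± 0.115 to 53.0 ± 21.5 CPM, the largest log2 fold change among genes named by the fixed rule (7.78, SE 0.49). Csf3, the granulocyte growth factor, rose by 6.75, Tnfsf9 by 5.71 and Il12b, a subunit of interleukin-12, by 5.05 on the log2 scale. Il6 rose 11.1-fold, from 4.45 ± 1.27 to 49.4 ± 12.3 CPM (adjusted p = 1.26e-05). Tnf rose 4.18-fold (adjusted p = 0.000748), and the anti-inflammatory Il10 rose 7.10-fold (adjusted p = 0.000811). Sham replicate 4 was the lowest sham library for 24 of the 34 genes, and without it 30 were higher and 1 lower. The single member that fell was Ccl6 (log2 fold change -0.36, adjusted p = 0.00628), named after its value was seen.

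All 28 NF-kB targets and feedback genes were higher (28 adjusted over the list alone, camera adjusted p = 2.47e-18, adjusted p = 0.217 with an estimated correlation), and with library totals 26 were higher and 0 lower. Sham replicate 4 was the lowest sham library for 26 of them, and without it all 28 were still higher in edgeR. Tnip3, a partner of A20, rose from 7.02 ± 4.30 to 410 ± 132 CPM. Nfkbia, which encodes the inhibitor IkB-alpha, rose 3.93-fold from 546 ± 109 CPM (log2 fold change 1.98, SE 0.14, adjusted p = 2.53e-06). Ptgs2, the inducible cyclooxygenase, rose 12.2-fold. Among pattern recognition receptors and adaptors 17 of 30 were higher and 7 lower (18 and 7 adjusted over the list alone, camera adjusted p = 0.00039, adjusted p = 0.217 with an estimated correlation). Clec4e rose 17.7-fold and Trem1 14.9-fold, whereas Tlr4, the lipopolysaccharide receptor, fell from 196 ± 33 to 62.2 ± 8.6 CPM (log2 fold change -1.66, adjusted p = 6.21e-06). Tlr4 was named after its value was seen.

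Genes that mark red pulp macrophages went both ways. Of 23 tested, 11 were higher and 5 lower (12 and 5 adjusted over the list alone), and the list did not pass the camera test (adjusted p = 0.0657, adjusted p = 0.568 with an estimated correlation), though it did without CLP replicate 3 (0.0325) or Sham replicate 1 (0.0154). With fold changes centred on the abundance trend, chosen after seeing the data, the list turned and was called lower (camera adjusted p = 2.53e-07). That test was run with the preset correlation only. Lower there means below the trend at like abundance, since the list's median log2 fold change was 0.22 with TMM scaling. With library totals 1 was higher and 8 were lower. Spic, the transcription factor that red pulp macrophages need to develop, rose from 1186 ± 118 to 2213 ± 370 CPM (log2 fold change 0.90, SE 0.12, adjusted p = 0.000166) and stayed higher with library totals (0.58). Vcam1, the most abundant member, was at 12610 ± 1181 CPM in sham and 16140 ± 1980 CPM in CLP (log2 fold change 0.36, adjusted p = 0.0196, but 0.04 and adjusted p = 0.734 with library totals). Its call was lost without CLP replicate 1 (adjusted p = 0.0612), CLP replicate 2 or Sham replicate 2. Adgre1, which encodes F4/80, and Sirpa, the receptor for the CD47 signal on red blood cells, were higher by 0.44 and 0.38 with TMM scaling and by 0.13 and 0.06, without a call, with library totals. The 5 lower members were Maf, Pparg, Mertk, Slc40a1 and Irf8. The transcription factor Maf fell from 746 ± 71 to 421 ± 115 CPM (adjusted p = 0.004), Pparg fell from 101 ± 7 to 67.4 ± 8.0 CPM, and the efferocytosis receptor Mertk, named after its value was seen like Irf8, fell 1.43-fold. The call of Irf8 was lost without CLP replicate 2 or 3 or without any single sham library, with adjusted p up to 0.0894. Vcam1 (log2 fold change 0.39, adjusted p = 0.0832), Maf (-0.55, 0.0528) and Irf8 (-0.43, 0.0767) also lost their calls with 1 surrogate variable in the fit. The hemoglobin-haptoglobin receptor Cd163 was at 1032 ± 82 CPM in sham and 925 ± 115 CPM in CLP and did not pass (adjusted p = 0.223), whereas with library totals it was called lower (-0.48, adjusted p = 0.000857).

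In the heme and iron group, 11 of 29 members were higher and 2 lower (11 and 3 adjusted over the list alone, camera adjusted p = 0.00411, adjusted p = 0.276 with an estimated correlation and 0.845 when centred on abundance), while 6 were higher and 9 lower with library totals. Hmox1, which encodes the heme-degrading enzyme, was at 5237 ± 940 CPM in sham and 5866 ± 1033 CPM in CLP, a difference within the replicate spread (log2 fold change 0.16, SE 0.15, adjusted p = 0.405, and -0.15 with library totals, adjusted p = 0.337). The heme transporter Slc48a1 did not pass either (0.15, adjusted p = 0.243, and -0.17 with library totals). Slc40a1, the iron exporter ferroportin, fell from 4514 ± 501 to 3414 ± 320 CPM (log2 fold change -0.40, SE 0.10, adjusted p = 0.0074). Bach1, a heme-sensing repressor of Hmox1, rose from 113 ± 15 to 675 ± 134 CPM (adjusted p = 1.73e-06). Steap4, a metalloreductase, rose from 0.635 ± 0.438 to 20.3 ± 7.4 CPM (log2 fold change 4.93, or 5.59 without Sham replicate 1), and Cp, the ferroxidase ceruloplasmin, rose 5.44-fold. Fth1, the ferritin heavy chain, rose 2.03-fold (adjusted p = 2.11e-05), and the other lower member was Aco1 (-0.26, adjusted p = 0.0178, lost without Sham replicate 1, 2 or 4, with adjusted p up to 0.0908). Fth1 and Aco1 were named after their values were seen. The calls of Slc40a1 (adjusted p = 0.108), Cp (0.0782) and Aco1 (0.313) were lost with 1 surrogate variable.

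**Figure D2:**
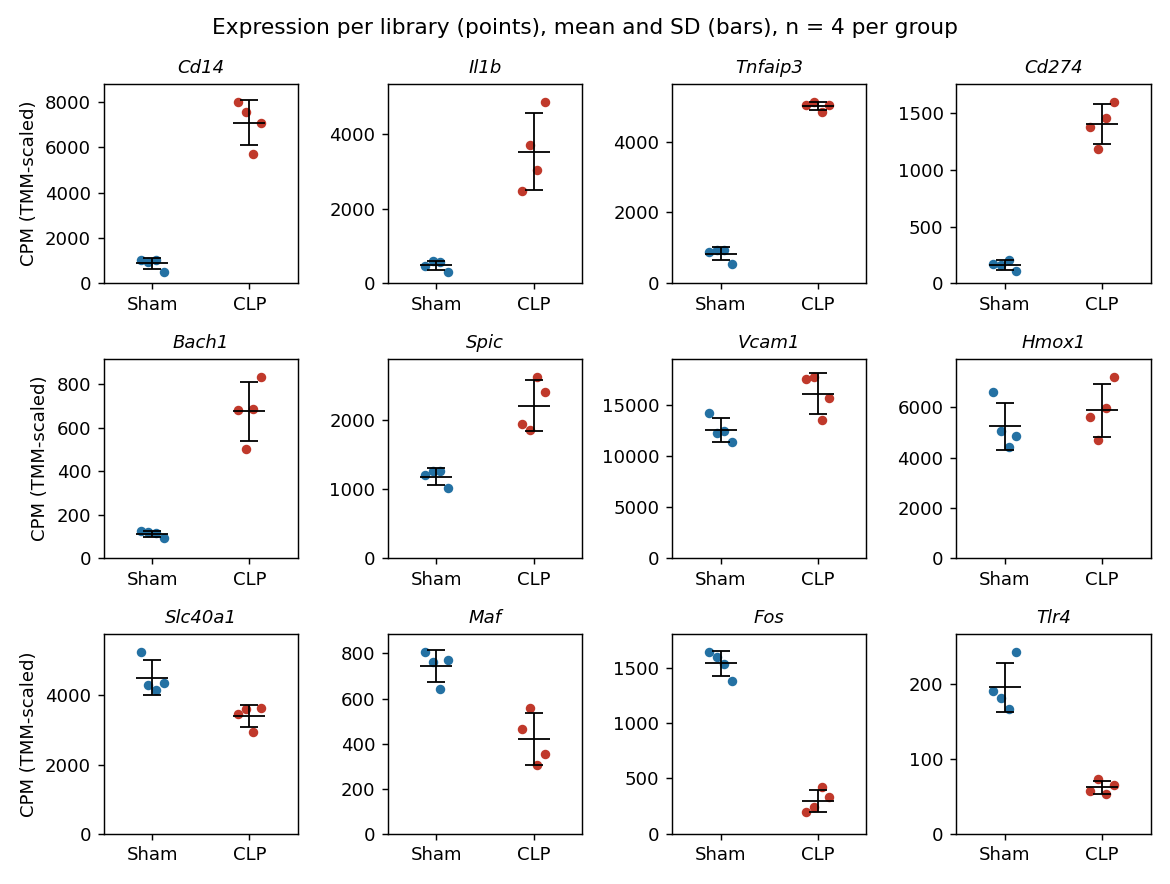
CPM with TMM scaling (axes start at 0) of 12 genes in each sham (blue) and CLP (red) library, with the mean and SD of 4 libraries per group as bars. Cd14, Il1b, Tnfaip3, Cd274, Bach1, Spic, Slc40a1, Maf, Fos and Tlr4 showed no overlap between the groups, whereas Vcam1 and Hmox1 overlapped.

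In the efferocytosis and erythrophagocytosis list, which holds receptors and other genes of these processes, 16 of 35 members were higher and 2 lower (16 and 2 adjusted over the list alone, camera adjusted p = 0.0018, adjusted p = 0.234 with an estimated correlation), but with library totals 5 were higher and 8 lower. The list's call was lost without genes shared with other lists (adjusted p = 0.0973), and its direction turned downward when centred on abundance (0.0597). The scavenger receptor Marco rose 2.50-fold (91.3 ± 22.4 to 228 ± 109 CPM, adjusted p = 0.0219) and the integrin Itgb3 rose 2.11-fold. Marco is also in the marginal zone macrophage marker list and Itgb3 in the platelet marker list. Whether other cells in the sort carried these 2 rises was not tested. Xkr8 and Mertk fell, Xkr8 with adjusted p = 0.0399 and up to 0.116 without CLP replicate 1 or 4 or any single sham library, and Xkr8 was named after its value was seen. In the lysosome and autophagy list 16 of 34 were higher and 4 lower (16 and 4 adjusted over the list alone, camera adjusted p = 0.00205, adjusted p = 0.39 with an estimated correlation), against 3 and 11 with library totals, and turned downward when centred on abundance (0.0566). The autophagy receptor Sqstm1 rose 2.81-fold from 611 ± 87 CPM. Tfeb, a transcription factor that drives lysosomal genes, fell 2.85-fold (log2 fold change -1.51, adjusted p = 1.45e-06) and Rubcn fell 2.81-fold. Atg16l1 and Atg5, named after their values were seen, were the other lower members, and Atg16l1 lost its call without CLP replicate 1, 2 or 4 or Sham replicate 2 or 3 (adjusted p up to 0.115), Atg5 without Sham replicate 1 or 3 (up to 0.0691). Ctsb, the most abundant member, was at 8059 ± 436 CPM in sham and 9374 ± 274 CPM in CLP, a log2 fold change of 0.22 (adjusted p = 0.0347, up to 0.103 without CLP replicate 1, 2 or 4 or Sham replicate 2 or 3) that became -0.10 with library totals. Marco (adjusted p = 0.245), Itgb3 (0.0571), Xkr8 (0.434) and Ctsb (0.164) lost their calls with 1 surrogate variable, and Marco (0.0693) also with no filter on low counts.

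The type I interferon list had 7 higher and 5 lower of 35 members (6 and 5 adjusted over the list alone) and did not pass camera (adjusted p = 0.258, adjusted p = 0.866 with an estimated correlation, but 0.0286 without CLP replicate 2), with 4 higher and 11 lower under library totals. Ifi205 rose 5.72-fold and Mx2 3.14-fold. The lower members were Ifit3b (-1.04), Ifit3 (-0.70), Ddx58, Irf9 and Dhx58, all 5 named after their values were seen. Ddx58 lost its call without CLP replicate 4 or Sham replicate 1, 2 or 3 (adjusted p up to 0.0814). Irf9 lost its own without any single library but CLP replicate 3 (up to 0.097), and Dhx58 without CLP replicate 2 or 4 or Sham replicate 1, 2 or 3 (up to 0.148). Mx2 (adjusted p = 0.0865), Ddx58 (0.0728) and Irf9 (0.101) lost their calls with 1 surrogate variable. In the interferon gamma list 11 of 23 were higher and 1 lower (11 and 1 adjusted over the list alone, camera adjusted p = 0.000256, adjusted p = 0.423 with an estimated correlation), and 8 and 3 with library totals. Cd274, which encodes PD-L1, rose from 161 ± 41 to 1405 ± 176 CPM (adjusted p = 3.26e-06), Socs1 rose 5.44-fold, and the lower member was Gbp8 (-0.62), named after its value was seen.

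MHC class II and co-stimulation genes were higher for 12 of 15 members (13 adjusted over the list alone) and lower for 0 in edgeR (camera adjusted p = 3.39e-06, adjusted p = 0.217 with an estimated correlation), and higher for 7 and lower for 0 with library totals. Cd40 rose 5.90-fold and Cd83 3.63-fold, while Cd74, the invariant chain and the most abundant member, rose 1.66-fold (adjusted p = 0.00877, 0.0606 with library totals). Of 24 complement genes 11 were higher and 1 lower (13 and 1 adjusted over the list alone, camera adjusted p = 0.00132, adjusted p = 0.217 with an estimated correlation and 0.608 when centred on abundance), and 4 and 3 with library totals. The receptors C5ar1 and C3ar1 rose 2.37-fold and 2.02-fold, and C5ar2 fell 2.49-fold. C1qc, the most abundant member, had a log2 fold change of 0.25 (adjusted p = 0.0369, up to 0.106 without CLP replicate 1, 2 or 4 or Sham replicate 2, 3 or 4) that became -0.07 with library totals. The calls of Cd74 (adjusted p = 0.116), C3ar1 (0.0553) and C1qc (0.104) did not hold with 1 surrogate variable. In the NADPH oxidase and reactive species list 12 of 16 were higher (12 adjusted over the list alone, camera adjusted p = 8.74e-06, adjusted p = 0.217 with an estimated correlation), and 6 higher and 2 lower with library totals. Arg2 rose from 1.64 ± 0.14 to 24.4 ± 6.0 CPM, the mitochondrial superoxide dismutase Sod2 rose 4.78-fold, and Cybb, the catalytic subunit of the oxidase, rose from 621 ± 39 to 935 ± 50 CPM.

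Immediate early genes split, with 15 of 27 higher and 6 lower (15 and 6 adjusted over the list alone, camera adjusted p = 0.0046, adjusted p = 0.533 with an estimated correlation), and 12 and 7 with library totals. When centred on abundance the list turned downward without passing (0.81). Maff rose 7.08-fold and Dusp5 6.04-fold. Fos fell from 1537 ± 113 to 297 ± 100 CPM (log2 fold change -2.37, SE 0.22, adjusted p = 4.99e-05). Fosb fell by 2.35 and Egr1 by 2.22 on the log2 scale, and Klf4, Nr4a2 and Btg2 were the other lower members, all 5 named after their values were seen. Btg2 (adjusted p = 0.0537) and the heat shock gene Hsph1 (0.0602) lost their calls with 1 surrogate variable. Among 20 heat shock genes 6 were higher and 2 lower (6 and 2 adjusted over the list alone, camera adjusted p = 0.549, adjusted p = 0.867 with an estimated correlation), against 5 and 11 with library totals. Dnajb4 rose 2.17-fold. Hsph1 (-0.88, adjusted p = 0.0382, up to 0.0983 without CLP replicate 1, 2 or 4 or Sham replicate 2, 3 or 4) and Dnajb1 (-0.82, named after its value was seen) fell. The median of this list was -0.10 and its mean 0.01, and its camera direction was upward. In the unfolded protein and integrated stress list 12 of 21 were higher and 1 lower (15 and 2 adjusted over the list alone, camera adjusted p = 0.000278, adjusted p = 0.234 with an estimated correlation and 0.199 when centred on abundance), and 4 and 2 with library totals. Ppp1r15a rose 2.19-fold, and Ddit3, which encodes the stress factor CHOP, fell 1.77-fold.

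Glucocorticoid-induced genes also went both ways, with 12 of 25 higher and 8 lower (12 and 8 adjusted over the list alone, camera adjusted p = 0.174, adjusted p = 0.574 with an estimated correlation). The metal-binding Mt2 rose from 2.27 ± 0.40 to 52.9 ± 17.4 CPM and Cdkn1a rose 7.76-fold, while Ddit4, an inhibitor of mTORC1, fell from 1000 ± 100 to 150 ± 32 CPM (adjusted p = 7.31e-07). Of 22 targets of IL-6, IL-10 and STAT3 18 were higher and 1, Il21r, was lower (18 and 2 adjusted over the list alone, camera adjusted p = 4.49e-07, adjusted p = 0.234 with an estimated correlation). Osmr rose 11.3-fold, and Il1rn, the antagonist of the IL-1 receptor, 11.1-fold. Il21r (-0.38) was named after its value was seen. Acute phase and antimicrobial genes were higher for 8 of 12 members (8 adjusted over the list alone, camera adjusted p = 0.000166, adjusted p = 0.217 with an estimated correlation), among them Cd14 and Mt2.

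NRF2 antioxidant genes were higher for 11 of 23 members and lower for 1 (12 and 1 adjusted over the list alone, camera adjusted p = 0.000115, adjusted p = 0.272 with an estimated correlation and 0.0661 when centred on abundance), and 8 and 5 with library totals. The cystine transporter Slc7a11 rose 23.4-fold from 2.76 ± 0.28 CPM and Txnrd1 4.09-fold. Keap1, which encodes the repressor of NRF2, fell 1.91-fold and was named after its value was seen. Of 26 glycolysis and hypoxia genes 12 were higher and 1 lower (13 and 2 adjusted over the list alone, camera adjusted p = 0.00133, adjusted p = 0.276 with an estimated correlation), but 8 and 7 with library totals. Adm rose 24.7-fold, hexokinase Hk2 3.93-fold and the glucose transporter Slc2a1 3.80-fold, and Slc2a3 was lower (-0.45, adjusted p = 0.031, up to 0.149 without CLP replicate 1, 3 or 4 or Sham replicate 1, 2 or 3), named after its value was seen. Of 33 nuclear genes for oxidative phosphorylation 6 were higher (3 adjusted over the list alone, camera adjusted p = 0.00195, adjusted p = 0.558 with an estimated correlation and 0.187 when centred on abundance), whereas 0 were higher and 10 lower with library totals. Cycs, 1 of the 6, lost its call with library totals (0.05, adjusted p = 0.78) and without CLP replicate 1, 3 or 4 or Sham replicate 1, 2 or 4 (adjusted p up to 0.124). Slc2a3 (adjusted p = 0.164) and Cycs (0.565) were not called with 1 surrogate variable.

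Cholesterol synthesis genes were higher for 12 of 21 members and lower for 1 (12 and 1 adjusted over the list alone, camera adjusted p = 6.9e-05, adjusted p = 0.217 with an estimated correlation), and 8 and 2 with library totals. Insig1 rose 2.53-fold from 66.1 ± 10.0 CPM, while Insig2, named after its value was seen, fell 1.54-fold. Among 19 targets of LXR, a sterol-sensing nuclear receptor, 10 were higher and 1 lower (13 and 1 adjusted over the list alone, camera adjusted p = 0.00772, adjusted p = 0.314 with an estimated correlation), and 3 and 6 with library totals, and turned downward when centred on abundance (0.995). The cholesterol exporter Abca1 rose 1.89-fold (799 ± 33 to 1507 ± 151 CPM), Arl4c rose 2.43-fold, and the exporter Abcg1 fell 1.95-fold (adjusted p = 6.11e-05). Apoe, at 2017 ± 106 CPM in sham, had a log2 fold change of 0.26 (adjusted p = 0.0235, 0.0741 without CLP replicate 1 and 0.194 with 1 surrogate variable) that became -0.06 with library totals.

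In the cell death list 11 of 28 were higher and 5 lower (11 and 5 adjusted over the list alone, camera adjusted p = 0.0141, adjusted p = 0.234 with an estimated correlation), and 8 and 11 with library totals. Its call was lost without genes shared with other lists (adjusted p = 0.091). The death receptor Fas rose 7.72-fold. Gsdme, Pycard, Bak1 and Aim2 were among the lower members and were named after their values were seen. Pycard, the inflammasome adaptor, fell 1.47-fold and Bak1 1.45-fold. Gsdme lost its call without any single library but CLP replicate 2 (up to 0.104), and Aim2 without any but CLP replicate 3 (up to 0.126). In the ribosome biogenesis list 10 of 28 were higher and 2, Rrp1b and Polr1a, lower (10 and 2 adjusted over the list alone, camera adjusted p = 0.0506, adjusted p = 0.635 with an estimated correlation), and 2 and 8 with library totals. The list passed camera without CLP replicate 1 or 2 or Sham replicate 1, 3 or 4 (adjusted p down to 0.00884). Gnl3 rose 2.13-fold, Ncl had a log2 fold change of 0.32 that was 0.00 with library totals, and Polr1a was named after its value was seen. Of 16 clock genes 4 were higher and 6 lower (5 and 6 adjusted over the list alone, camera adjusted p = 0.964, adjusted p = 0.972 with an estimated correlation), and 1 and 8 with library totals. The 4 were Nfil3, Cry2, Nr1d2 and Rora. Nfil3 rose 6.25-fold and Bhlhe41 fell (-1.04), while Cry2 and Nr1d2, named after their values were seen, lost their calls without CLP replicate 1 (adjusted p = 0.0505 and 0.0515), and Rora lost its own without CLP replicate 2 (adjusted p = 0.0905) or Sham replicate 3. Dbp fell 1.80-fold (adjusted p = 0.0189) and lost its call without Sham replicate 1 or 2 (up to 0.0647). Gsdme (adjusted p = 0.29), Aim2 (0.0709), Bhlhe41 (0.176), Cry2 (0.177), Nr1d2 (0.22) and Dbp (0.314) lost their calls with 1 surrogate variable, and Cry2 (0.47), Nr1d2 (0.612) and Rora (0.804) with library totals.

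Of 30 genes of S phase and mitosis 0 passed in edgeR, 0 were below an unadjusted p of 0.05, and DESeq2 and limma-voom called 0 as well (0 adjusted over the list alone, camera adjusted p = 0.469), while 4 were lower with library totals. All 30 were highest in Sham replicate 4 among the sham libraries. Mki67, a marker of cycling cells and the most abundant member, was at 402 CPM there and at 57.0 to 118 CPM in the other sham libraries, against 176 ± 37 CPM in CLP. Its log2 fold change was 0.13 with all libraries (adjusted p = 0.893) and 1.15 without Sham replicate 4 (adjusted p = 0.0105).

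**Figure D3:**
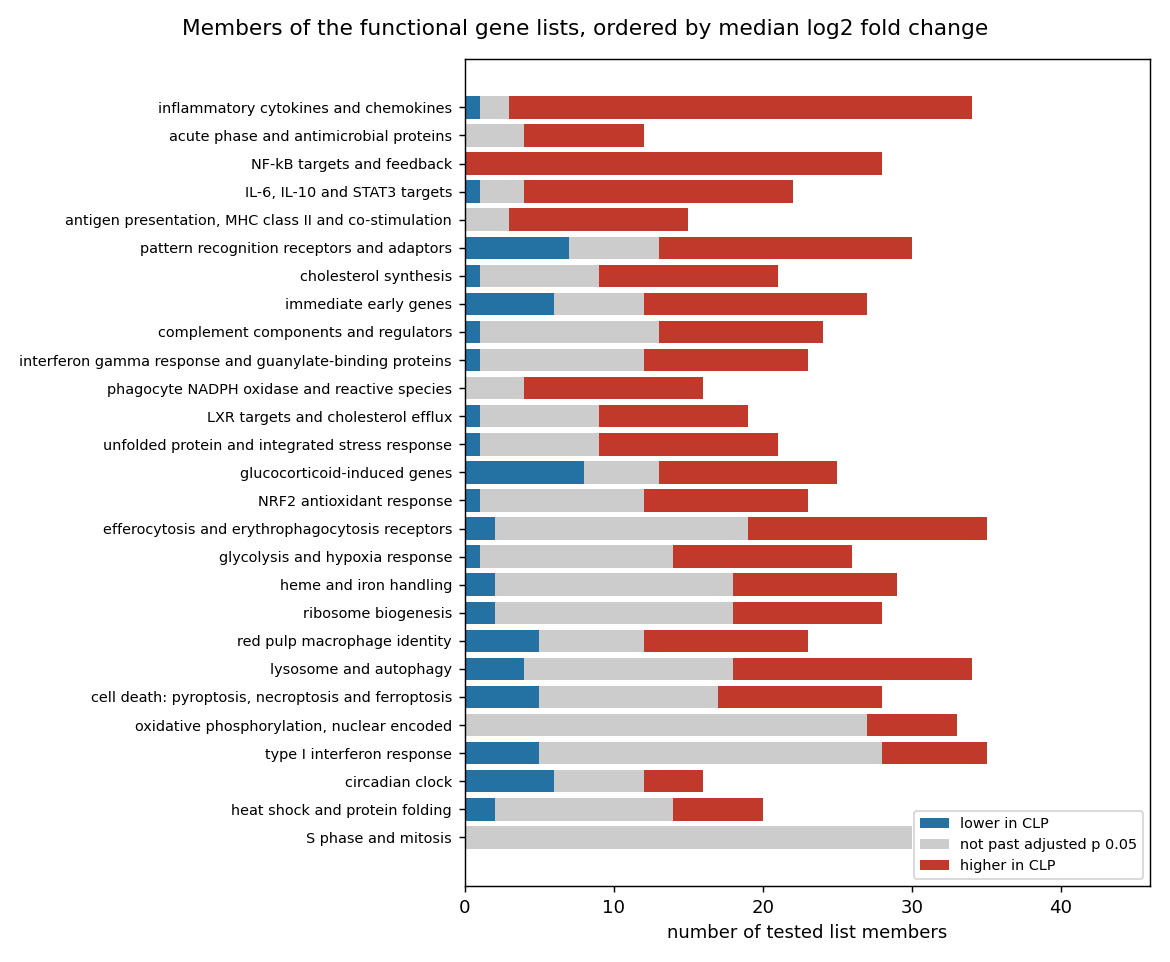
Bars give the number of tested members of each of 27 functional gene lists that were lower (blue), not past adjusted p 0.05 (grey) or higher (red) after CLP with TMM scaling, ordered by median log2 fold change. All 28 NF-kB members were red, and the red pulp macrophage identity list held 11 red and 5 blue members, against 1 and 8 with library totals.

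The genes with the lowest fold changes under the fixed rule were mostly scarce. Lpar5, a lysophosphatidic acid receptor, fell from 12.8 ± 3.2 to 1.78 ± 0.67 CPM (log2 fold change -2.84, SE 0.27, adjusted p = 1.47e-05). The zinc-finger genes Zfp324, Zfp60 and Zfp961 fell 7.11-fold, 5.83-fold and 5.22-fold, and Klhl42, Trim47 and Rab39 fell 5.92-fold, 5.81-fold and 5.75-fold. At the other end stood the ion channel gene Hcn4 (39.9-fold higher) and the endothelin receptor gene Ednrb (33.1-fold higher), each below 1 CPM in every sham library.

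Several markers of other cells were higher after CLP. Of 17 neutrophil markers only 5 had enough counts to be tested. Of these, 4 were higher, S100a8, S100a9, Csf3r and Il1r2 (4 adjusted over the list alone, camera adjusted p = 0.0277, adjusted p = 0.425 with an estimated correlation). Il1r2 is also in the glucocorticoid list. The call of the neutrophil list was lost without any single CLP library, Sham replicate 1 or Sham replicate 4 (adjusted p up to 0.255) or when centred on abundance (0.0913), and that of Csf3r with library totals (0.17, adjusted p = 0.329). S100a9 was at 2.06 ± 1.12 CPM in sham and 9.90 ± 5.64 CPM in CLP. Of 12 platelet markers 8 were higher and Vwf was lower (9 and 1 adjusted over the list alone, camera adjusted p = 0.00112, adjusted p = 0.107 with an estimated correlation), with Gp5 at 0.205 ± 0.087 against 0.989 ± 0.380 CPM. The fall of Vwf lost its call without Sham replicate 3 (adjusted p = 0.0809) or Sham replicate 4. Fibroblastic stromal markers were higher for 7 of 10 members (7 adjusted over the list alone, camera adjusted p = 0.00536, adjusted p = 0.425 with an estimated correlation), such as Acta2 at 1.07 ± 0.38 against 2.89 ± 1.11 CPM and Cxcl12 at 25.5 ± 5.2 against 43.0 ± 7.9 CPM. Marginal zone and metallophilic macrophage markers were higher for 6 of 10 members (6 adjusted over the list alone, camera adjusted p = 0.00536, adjusted p = 0.295 with an estimated correlation and 0.826 when centred on abundance), and 4 higher and 1 lower with library totals. Some of these markers, Fcna among them, are also in the red pulp macrophage identity list, so this list does not mark other cells alone. Fcna, its most abundant member, had a log2 fold change of 0.29 that became -0.03 with library totals and lost its call without CLP replicate 1 (adjusted p = 0.0534) or Sham replicate 2. S100a8 (adjusted p = 0.0525), S100a9 (0.0576), Csf3r (0.166), Acta2 (0.0509) and Fcna (0.0887) were not called with 1 surrogate variable.

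Of 17 erythroid markers 4 were higher, among them Hbb-bs, Hbb-bt and Alas2 (4 adjusted over the list alone, camera adjusted p = 0.135), and 2 with library totals, where Hbb-bt lost the call. Hbb-bs, a hemoglobin gene whose reads can be shared with its near copy Hbb-bt, was at 46.7 ± 19.6 CPM in sham and 138 ± 42 CPM in CLP (adjusted p = 0.00477). Without Sham replicate 4, the sham library richest in this list, 9 were higher, and Slc4a1 went from a log2 fold change of 0.11 to 1.05 (adjusted p = 0.0275) and the list passed camera (adjusted p = 0.000276), against adjusted p = 0.715 with an estimated correlation in all 8 libraries. Hbb-bt lost its call without CLP replicate 3 (adjusted p = 0.0725) or Sham replicate 3 and with 1 surrogate variable (0.0562).

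The conventional dendritic cell list had 4 higher, Zbtb46, Ccr7, Fscn1 and Batf3, and 1 lower, Clec9a, of 12 (4 and 1 adjusted over the list alone, camera adjusted p = 0.402), but 2 higher and 3 lower with library totals, and the plasmacytoid list 2 higher, Bst2 and Runx2, of 8 (2 adjusted over the list alone, camera adjusted p = 0.221), or 1 higher and 1 lower with library totals. Plasma cell markers had 2 higher of 7 (2 adjusted over the list alone, camera adjusted p = 0.377), Sdc1 and Prdm1, a transcription factor gene at 114 ± 35 CPM in sham and 659 ± 85 CPM in CLP. Of 16 B cell markers only Cd79b changed and was lower (1 adjusted over the list alone, camera adjusted p = 0.977), of 16 T cell markers only Ccr7 changed and was higher (1 adjusted over the list alone, camera adjusted p = 0.221), and of 13 monocyte markers only Fn1 changed and was higher (0 adjusted over the list alone, camera adjusted p = 0.483), a call lost with library totals. Among 11 NK cell markers Rora was higher and Ncr1 lower (0 and 1 adjusted over the list alone, camera adjusted p = 0.977), against 0 and 2 with library totals. The list's median was 0.08 while its mean was -0.06 and its camera direction downward. Ncr1 averaged below 1 CPM in both groups (0.873 ± 0.265 CPM in sham and 0.207 ± 0.043 CPM in CLP), where counting error is large. Among 8 endothelial markers Lyve1 was higher and Vwf lower (1 and 1 adjusted over the list alone, camera adjusted p = 0.398), against 1 and 3 with library totals. Pecam1, the most abundant endothelial marker, was at 435 ± 42 CPM in sham and 481 ± 14 CPM in CLP, did not pass (adjusted p = 0.169), and was called higher without Sham replicate 1 (adjusted p = 0.0433) and lower with library totals (-0.17, adjusted p = 0.0453). Only 3 mast cell and basophil markers were tested, too few for camera, and Kit was higher (1 adjusted over the list alone). S100a8, Hbb-bt, Alas2, Zbtb46, Batf3, Clec9a, Bst2 and Sdc1 were named after their values were seen. Batf3 lost its call without CLP replicate 1, 3 or 4 or Sham replicate 1, 2 or 4 (adjusted p up to 0.112), and Clec9a without CLP replicate 1 or 2 or Sham replicate 2, 3 or 4 (up to 0.101). Fn1 lost its call without CLP replicate 2 (0.0503), Sdc1 without CLP replicate 3 (0.0563), and Kit without CLP replicate 1, 3 or 4 (up to 0.0597). Zbtb46 (adjusted p = 0.0971), Clec9a (0.131), Batf3 (0.752), Runx2 (0.0853), Sdc1 (0.0753), Cd79b (0.0551) and Kit (0.188) lost their calls with 1 surrogate variable. Zbtb46 (0.0807), Batf3 (0.375), Bst2 (0.124) and Kit (0.42) lost theirs with library totals.

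Mitochondrially encoded transcripts were higher for 8 of 9 members (8 adjusted over the list alone, camera adjusted p = 0.00171, adjusted p = 0.295 with an estimated correlation) and ribosomal protein transcripts for 22 of 32 (28 adjusted over the list alone, camera adjusted p = 1.94e-06, adjusted p = 0.539 with an estimated correlation), but 0 of either list were called in either direction with library totals. The median log2 fold changes of these lists were 0.30 and 0.26 with TMM scaling and -0.02 and -0.06 with library totals, where mt-Co1 had -0.02 and Rpl4 0.03. The TMM medians were of the size of those of the heme and iron (0.23), efferocytosis (0.25), lysosome (0.20) and LXR (0.31) lists. Both lists turned downward when centred on abundance (adjusted p = 0.795 and 0.826), and Rpl4 lost its call with 1 surrogate variable (0.0506). Of the 4 nuclear retained RNAs tested 0 passed in edgeR, 0 had an unadjusted p below 0.05, and 0 passed in DESeq2 or limma-voom (1 with sample weights, 0 adjusted over the list alone). Malat1 was at 10190 ± 1847 CPM in sham and 10770 ± 1469 CPM in CLP. The Y-linked gene Ddx3y was present in all 8 libraries, from 86.0 to 180 CPM, and was higher after CLP (adjusted p = 2.11e-05). Kdm5d and Uty, both named after their values were seen, were lower (1 higher and 2 lower of 4, or 2 and 2 adjusted over the list alone). The call of Uty was lost without CLP replicate 1 or 4 or any single sham library (adjusted p up to 0.111) and with 1 surrogate variable (0.215).

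By camera with a preset correlation of 0.01, 20 of 27 functional lists and 6 of 15 marker lists were higher and 0 of either were lower, and 0 of either passed with an estimated correlation (4 and 2 at an unadjusted p below 0.05), while fry called 18 and 8. Centred on abundance, with the preset correlation, 12 and 2 lists passed, the identity list among them as lower. Without genes shared with other lists, 17 of 26 functional and 5 of 14 marker lists passed. Efferocytosis and cell death lost their calls there, and the acute phase and neutrophil lists had too few genes left to test.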

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

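All tests of explanations in this part except the counts over all 35 splits were chosen after the result was seen. Of 35 splits of the 8 libraries into 4 and 4, only 1, the real split, gave as many as 6064 changed genes or 2053 genes changed at least 2-fold. The highest of the other splits was 0 for both. A share of 1 in 35 is the smallest these splits allow. The other splits put CLP and sham libraries on the same side, which widens the spread within their groups and makes low counts likely from the start. They also cannot tell CLP from a processing step that ran with the groups. For the 20 functional lists, 7 of 35 splits gave as many, with 24 the highest other count, and for the 6 marker lists 9 of 35 did, with 9 the highest, so these shares do not exclude chance for the list counts. They do not measure chance alone either, since the 6 other splits with at least 20 functional lists and 7 of the 8 with at least 6 marker lists kept 3 libraries of each group together. Among the 18 splits with 2 libraries of each group on both sides, the highest counts were 17 functional and 6 marker lists.

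Single libraries lay far from the other 3 of their group in 18 of 330 groups of 4 checked, where chance flags about 1 in 20, or 16.5. Sham replicate 4 held 6 of these. It was lowest for Il6 (2.55 CPM, the others 4.98 to 5.24), Ptgs2 (29.4 CPM against 49.2 to 49.9), Tnfaip3 (556 CPM against 894 to 952), Trem1 (1.40 CPM against 3.25 to 3.38) and Thbd (7.94 CPM), and highest for Alas2 (171 CPM against 86.2 to 97.3). CLP replicate 3 was lowest for Ptgs2 (323 CPM), Nfil3 (241 CPM) and Cd79b (15.9 CPM) and highest for Hbb-bt (35.2 CPM) and Alas2 (520.1 CPM). CLP replicate 2 was lowest for Csf3 (78.8 CPM) and highest for Rora (27.3 CPM). Sham replicate 1 was highest for Cxcl3 (0.398 CPM) and Gsdme (1.74 CPM) and lowest for Ddit3 (6.22 CPM). Sham replicate 3 was highest for Mx2 (26.9 CPM) and lowest for Dbp (5.65 CPM).

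Sham replicate 4 stood apart in a wider sense. All 17 erythroid markers and all 30 S phase and mitosis genes were highest there among the sham libraries, while 24 of 34 cytokine genes and 26 of 28 NF-kB genes were lowest. Dilution of macrophage RNA by other cells would lower macrophage genes as much as inflammatory ones, but the identity list had a median log2 ratio of -0.06 to the other sham libraries against -0.65 for the cytokine list. Erythroid cells in that sort could account for the erythroid part, which had a median log2 ratio of 2.26, but Hbb-bs was at 74.1 CPM beside 902 CPM for Slc4a1, the reverse of what red cell precursors hold. Hbb-bs also lay below Slc4a1 in every other library, so this order is not particular to Sham replicate 4. Because counting may drop reads shared by near-identical hemoglobin genes, the explanation by erythroid cells stays open, and no biological explanation was tested. Other sham libraries were one-sided too, by smaller medians. Sham replicate 3 was highest for 24 cytokine genes (median log2 ratio 0.45) and 26 NF-kB genes (0.37). Sham replicate 1 was lowest for 15 erythroid markers (-1.18) and 16 cell cycle genes (-0.86), and highest for 18 of 23 identity genes (0.17).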

How the results depend on the processing

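The surrogate-variable and library-total fits were planned, and the abundance-centred lists and the filter at 10 CPM were chosen after seeing the data. The number of changed genes lay between 5077 and 6250 with 1 library left out and between 5891 and 6761 in the other planned fits that kept TMM-like scaling and no surrogate variable, with library totals giving 7721. With 1 surrogate variable it was 3550 (1590 higher, 1960 lower). On simulated counts that fit recovered 19.4% of 1.5-fold and 80.6% of 2-fold changes, against 50.7% and 95.5% in edgeR. No hidden factor was simulated, and whether this lower power is the whole cause of the lower count was not tested. Where named genes lost their call there, some log2 fold changes grew (Acta2 1.40 to 1.65, Hsph1 -0.88 to -1.18) and others shrank (Batf3 0.50 to 0.08, Cycs 0.37 to 0.15). Library totals gave 1286 higher and 6435 lower genes, 570 and 2127 of them at least 2-fold, because they shift all fold changes by a median of -0.32. Of the 6064 genes called in the main fit, 4584 were called there too. All but 1 of these (4583) kept their direction, which a near-constant shift of the same counts makes likely in advance. A mean of at least 10 CPM leaves fewer genes to test and turned the balance, with 2255 higher and 1894 lower genes (54.4% higher) and 768 changed at least 2-fold (490 higher, 278 lower). With 1 library left out, genes changed at least 2-fold numbered 1911 to 2207, higher genes 2310 to 2847, lower genes 2639 to 3458, and the 2-fold sets 840 to 1024 higher and 1021 to 1282 lower. The first component held 77.0% to 81.5% of the variance in these fits. The labels do not say whether the replicate numbers pair the libraries. Correlations of same-numbered deviations were 0.07, -0.04, 0.26 and -0.19, which leaves this open. A fit with the number as a block called 6089 genes, 2054 at least 2-fold, with 22 functional and 6 marker lists.

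With an estimated correlation 0 functional and 0 marker lists passed. Abundance-centred tests, run with the preset correlation only, called 12 and 2, since abundant genes sat above 0 (median 0.35 above 300 CPM) and scarce ones below (-0.30 from 2 to 10 CPM). That centring turned the direction of 12 lists, 7 of which passed at least 1 of the 2 tests: identity (adjusted p = 2.53e-07, lower), efferocytosis (0.0597), immediate early (0.81), lysosome (0.0566), LXR (0.995), mitochondrial (0.795) and ribosomal protein (0.826). The other 5, heat shock, glucocorticoid, clock, B cells and NK cells, passed neither. With 1 library left out, 20 to 22 functional and 5 to 6 marker lists passed. Without genes shared with other lists, 17 of 26 and 5 of 14 did, as efferocytosis (0.0973) and cell death (0.091) lost their calls and the acute phase and neutrophil lists had too few genes left. By fry, immediate early (0.0683) and oxidative phosphorylation (0.0622) lost theirs. Of 164 named genes, 30 of 155 called lost the call without at least 1 library, 42 with 1 surrogate variable (adjusted p 0.0506 to 0.752, each given beside its result) and 10 with no filter on low counts (C1qc, Cd74, Ctsb, Cycs, Gsdme, Hbb-bt, Hsph1, Kit, Marco and Rora, up to 0.116). DESeq2 lost Aim2, Dhx58, Gsdme and Uty, its size factors in edgeR Aim2, Dhx58 and Irf8, sample weights Batf3 (while calling Slc48a1 higher), and the block Batf3, Csf3r, Cycs, Gsdme and Xkr8. Of the named genes without a call in the main fit, DESeq2 called 1, limma-voom 2, sample weights 3 and the block 2. Library totals ended 22 calls, and with them C1qc (-0.07), Ctsb (-0.10), Apoe (-0.06), Ncl (0.00), Fcna (-0.03), mt-Co1 (-0.02) and the uncalled Pecam1 (-0.17), Hmox1 (-0.15), Slc48a1 (-0.17), Mki67 (-0.22), Slc4a1 (-0.23) and Malat1 (-0.24) lost or changed their sign. Totals of 15392992 to 25665633 counts limit statements on genes below about 1 CPM.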

Other observations

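The genes of this paragraph lie outside the fixed lists and were chosen after their values were seen. No list of coagulation genes, or of prostaglandin or adenosine receptors, was tested. Plaur, the urokinase receptor, rose 8.40-fold (5.01 ± 0.71 to 42.1 ± 8.2 CPM, adjusted p = 6.76e-07 in edgeR), Procr, the receptor of protein C, 8.70-fold, and Thbd, thrombomodulin, 5.35-fold. Thbs1 rose 4.72-fold. Ptger4, a prostaglandin E2 receptor, rose from 105 ± 28 to 365 ± 49 CPM, and of the adenosine receptors Adora2a rose 5.32-fold and the scarce Adora2b 10.3-fold (log2 fold change 3.36, or 4.11 without Sham replicate 3).

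The tests of the patterns that follow were chosen after the results were seen. Zinc-finger genes (374 with symbols of the Zfp, Zkscan, Zscan or Zbtb type) were lower as a class after CLP, with 255 lower and 26 higher and a median log2 fold change of -0.82, and 309 lower and 14 higher with library totals. Scarce genes as a whole sat below 0, but the class lay -0.70 from genes of like abundance, and 0 of 10000 random lists of such genes were as low. Matching on transcript length and GC content as well left -0.61, again with 0 of 10000 lists as low. The random lists draw unrelated genes and do not allow for zinc-finger genes varying together between libraries, so these counts overstate the evidence. An effect of CLP on this class stays open as a hypothesis, found and tested on the same data.

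Fos, Fosb, Egr1, Klf4, Nr4a2 and Btg2 had a median log2 fold change of -1.90 while 15 other immediate early genes rose. The abundance trend does not account for it, since its median at these 6 genes was 0.38. Less handling stress in the CLP samples could lower these genes, and it cannot be told apart from an effect of CLP here. Of 20 heat shock genes 2 were lower and 6 higher with TMM scaling, but 11 lower and 5 higher with library totals, which shift all genes downward. Hspa1a (-0.67, adjusted p = 0.0751 in edgeR) and its near copy Hspa1b (-0.82, adjusted p = 0.089), chosen after their values were seen, passed in limma-voom and with library totals (adjusted p = 0.0135 and 0.0239), and Hspa1a without CLP replicate 3 (0.0495).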
